A study of Sarcophaga bullata with 16 samples.

How the data were processed

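Sarcophaga bullata were reared at 25 °C with 15 h of light and 9 h of dark, and total RNA was taken from pools of 4 pharate adults, per the labels' protocols. From 500 ng of RNA, Cy3- or Cy5-labelled cRNA was made by linear amplification and hybridised to 2-colour oligonucleotide arrays, per the labels' protocols. The labels number 19 RNA pools, 5 of them controls, and 4 control pools stand on more than 1 array. The series text gives 4 biological replicates per treatment, while the labels number up to 5 pools of a treatment. Pools within a comparison were of different flies as far as the numbering shows. The p-values measure the spread between arrays, which holds differences between pools and differences between arrays. In the residuals of the model described below, the array variance was 0.0223, against 0.00396 for control pools and 0.0052 for treated pools. The spread was estimated over all comparisons together, and some pools stand in more than 1 comparison, so the arrays behind it are not all independent.

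The scanner output gives median signal intensities of each spot and of its local background in both channels, which the authors deposited with no normalization, per the file headers. Intensities called processed signals in these files were background-subtracted, detrended and dye-normalized within the array by Agilent Feature Extraction under protocol GE2-v5_10_Apr08, per the file headers. Its log10 ratio of Cy5 over Cy3 was computed from those processed signals, per the file headers. The headers name version 10.1.1.1 of the software and the submitters' processing notes name version 9.5. The table of log2 ratios that the authors deposited for the whole series came with no stated method. Set against the log2 ratios recomputed and normalized here as described below, its columns had slopes of 0.903 to 1.14 and correlations of 0.988 to 1.00 in size. Its own medians were -0.00684 to 0.00779. Its scale and centring were thus base 2 and near 0, it ran with the treatment named second in each title as numerator, and it was used as an alternative.

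Ratios were recomputed from the median signals, since one file gives no mean signal, with R 4.3.3 and limma 3.58.1. Background was corrected by normexp with an offset of 50, each array was normalized by loess, control spots and spots marked by the scanner software as outliers had weight 0 in loess, and outlier spots were then left out. Saturated spots, 0 to 4 per array, were kept. One step was added after first results had been seen. On 5 arrays, 9 channels held 3 to 21 spots with a local background far above their own signal, and the fitted normexp mean of these channels lay between -930 and -98, while the other channels had means of -12.0 to 4.05. Local backgrounds that the scanner software marks as non-uniform outliers, 0 to 62 per channel, were therefore replaced by the channel's median background, after which all means lay between -16.6 and 4.08. The results without this step are among the alternatives.

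Of 43803 probes, 25219 were well above background in at least 1 channel on at least 4 arrays. For 2 of these a coefficient could not be estimated, which left 25217. No probe has a gene name or a description in the files, no annotation was used here, and no gene was named from a sequence or an identifier. Transcript names are those that the files give, contig-style for most probes and database accessions, not printed here, for a small part. The 28 gene lists fixed beforehand (heat shock proteins and chaperones, immunity, cytoskeleton, muscle, cuticle, sugar and polyol metabolism, respiration, antioxidants, cytochrome P450, proteasome, apoptosis, autophagy, stress signalling, unfolded protein response, lipid and amino acid metabolism, cold-associated genes, ribosome, translation, ecdysone, clock, cell cycle and 5 sets of tissue markers) matched 0 probes, so their tests were void.

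All 16 arrays were fitted in one limma model of log2(Cy5/Cy3) with one coefficient per comparison, entered as 1 or -1 by dye orientation, and a dye intercept per probe, which left 11 residual degrees of freedom. Each comparison rests on its own 4 arrays, and the 4 comparisons share the estimate of the spread. Moderated tests were two-sided with Benjamini-Hochberg adjustment over all tested probes, at a threshold of 0.05. The differences between CS+2R over C and RCH over C, and between RCH+CS+2R over C and CS+2R over C, were contrasts of the same model. Values per probe are means ± SD of the 4 normalized log2 ratios, turned so that the first-named treatment is the numerator. The tests were tried on simulated data with the real spread, in which 66 or 67 probes were changed at each of 3 sizes (0.5, 1 and 2 on the log2 scale) per comparison. The simulated noise was drawn independently for each array, with no shared pools.

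The model, the named-probe rule and the other alternatives were fixed before the data were examined. The rule takes, among probes past the threshold with the same sign on all 4 arrays and with the brightest such probe standing for its transcript name, the 2 largest rises and 2 largest falls per comparison. Where fewer than 5 probes qualified, the probes with the smallest p were given and said not to pass. The alternatives were no background subtraction, a normexp offset of 0, processed signals, median centring, scaling between arrays, the deposited log2 table, no filter and a stricter filter on dim probes, outlier spots kept, no dye term, the arrays of a comparison alone, the replicate number as a block, the control pool as a random block, array weights, the slide as a block, a joint model of the 4 treatments, a minimum change of 2-fold, trended and robust empirical Bayes, each array left out in turn and, for correlations, the control pools split. Slide and scan batch came from the file headers: 7 slides, none with more than 1 array of a comparison, and 2 scan batches, one of which held 1 array, RCH vs C replicate 2. That array and CS+2R vs C replicate 3 each lay alone on a slide. With the slide as a block they therefore added nothing to the estimates. Pool and array variances for the simulation of unchanged groups came from the residuals of the model. Figures were drawn with matplotlib 3.10.9.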

Results

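Whole pharate adults of the flesh fly Sarcophaga bullata, developing adults still enclosed in the puparium and taken at the red-eye stage, were exposed to cold in 4 ways and their RNA was compared on 2-colour oligonucleotide arrays. Control flies (C) stayed at 25 °C. Flies given rapid cold-hardening (RCH), a brief mild chill that raises tolerance of a later severe one, spent 2 h at 0 °C. Cold-shocked flies (CS+2R) spent 2 h at -10 °C followed by 2 h of recovery at 25 °C, and a last group (RCH+CS+2R) received the hardening step before the same shock and recovery. Each RNA pool came from 4 flies. The 16 arrays made up 4 direct comparisons of 4 arrays each: each of the 3 cold treatments against C, and RCH+CS+2R against CS+2R. Within a comparison every array carried a different pool on each side, and the treated pool was in Cy5 on 2 arrays and in Cy3 on 2.

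The 4 arrays of a comparison set the precision of its values. The median signal of an array was 1.51 to 1.79 times its median background in Cy3 and 1.40 to 1.60 times in Cy5, and 49.3% to 58.0% of probes lay well above background in a channel. Of 43803 probes, 25217 were tested, under 14432 transcript names. The files pair no probe with a gene name or a description, so transcripts are given by probe ID, and the 28 gene lists fixed before the data were examined matched 0 probes and gave no test. At the median standard error, a log2 fold change in RCH flies had a 95% interval of ±0.158. Spike-in RNA gave Cy5 over Cy3 log10 ratios between -0.20 and -0.02 on 13 arrays, and 2.05, -1.25 and -1.36 on CS+2R vs C replicate 4, RCH+CS+2R vs C replicate 1 and RCH+CS+2R vs CS+2R replicate 2.

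**Figure D1:**
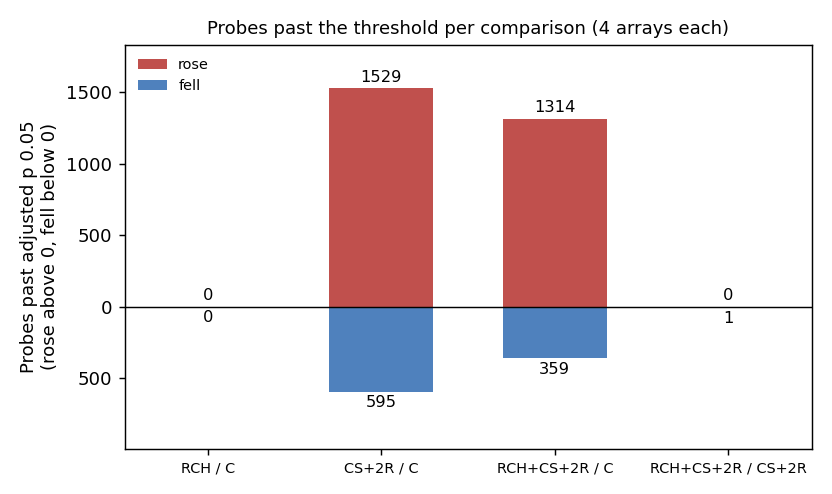
Probes past a limma adjusted p of 0.05 in each comparison of 4 arrays, with the number that rose drawn above 0 and the number that fell drawn below it. The comparisons of cold-shocked flies with controls hold 1529 rising and 595 falling probes without prior hardening and 1314 and 359 with it, RCH against C holds 0, and RCH+CS+2R against CS+2R holds 1 falling probe.

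The comparison of RCH with C asked which transcripts had changed by the end of the hardening chill itself. No transcript passed the test. limma called 0 of 25217 probes, and 1251 probes (4.96%) had an unadjusted p under 0.05. The rise with the smallest p was that of UF_Scr_NF_100051, with a log2 ratio of 1.18 ± 0.52 (SD, n = 4) that was above 0 on all 4 arrays and did not pass (limma adjusted p = 0.454). UF_Scr_AF_122852 had a log2 ratio of 0.77 ± 0.24 (SD, n = 4) and the same adjusted p of 0.454. Among probes with negative ratios the smallest p values belonged to UF_Scr_AF_107845, at -0.41 ± 0.12 (SD, n = 4), and UF_Scr_AF_122896, at -1.08 ± 1.08 (SD, n = 4), neither of which passed (limma adjusted p = 0.454 for each). Of these 4 probes, UF_Scr_NF_100051 passed under 3 of 35 alternatives and UF_Scr_AF_122852 under 1. The log2 ratios of the 4 arrays correlated across probes with r between -0.31 and 0.29. For 7960 transcripts measured by 2 probes, the fold changes of both probes correlated with r = 0.471 across transcripts, inside the range of 0.345 to 0.610 that the 7 other sign patterns of the 4 arrays gave. Simulated data with the same design and residual spread were also tested. There, 91.0% of probes changed by 0.5 on the log2 scale and 100% of those changed by 1 were recovered. The simulated noise was independent between arrays, with no shared pools, and many changed probes were planted together, which eases the adjusted threshold. The recovery thus does not show that a lone change of 1 would pass, and UF_Scr_NF_100051 and UF_Scr_AF_122896 did not. With the slide as a block 8 probes passed, from the arrays of this comparison alone 3 passed, and without the 3 arrays that stood apart in spike-in ratio 2 passed. The slide block takes up replicate 2, which lay alone on its slide.

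The comparison of CS+2R with C asked what 2 h of recovery from cold shock looked like in the transcriptome. Of 25217 probes, 2124 passed the test, 1529 that rose and 595 that fell, under 1662 transcript names. Rises were also the larger changes: 96 probes rose and 3 fell by at least 2-fold, and the called changes ran from -4.67 to 4.85 on the log2 scale. UF_Scr_NF_100073 rose by 3.93 ± 0.18 (SD, n = 4) on the log2 scale, a 15.2-fold increase (limma adjusted p = 2.33e-17). Its 60-base probe is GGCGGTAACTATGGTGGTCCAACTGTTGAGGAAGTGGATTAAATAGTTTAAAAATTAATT. UF_Scr_NF_100094 (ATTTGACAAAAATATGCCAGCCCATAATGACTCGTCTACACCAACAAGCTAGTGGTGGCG) rose by 3.55 ± 0.15 (SD, n = 4), or 11.8-fold (limma adjusted p = 3.93e-15). In RCH flies these probes had log2 ratios of 0.07 ± 0.13 and 0.06 ± 0.17 (SD, n = 4).

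The fall of UF_Scr_AF_114530 (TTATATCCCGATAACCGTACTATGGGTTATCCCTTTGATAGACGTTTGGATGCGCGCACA) was the largest of any called probe, at -4.67 ± 0.20 (SD, n = 4) on the log2 scale, or 25.5-fold lower in CS+2R (limma adjusted p = 3.62e-17). The size of this fall depended on the background offset, and was -5.46 with an offset of 0 and -5.90 with processed signals. It stayed well above background in the shocked flies on all 4 arrays. The next transcript in size of fall, measured by UF_Scr_AF_118902 (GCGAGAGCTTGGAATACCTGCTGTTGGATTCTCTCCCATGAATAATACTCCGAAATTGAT), had a log2 ratio of -1.10 ± 0.31 (SD, n = 4), 2.14-fold lower (limma adjusted p = 8.90e-08). Of the 2124 called probes, 1835 had the same sign on all 4 arrays. Among 1060 transcripts with 2 probes and a call on either, 323 had both probes rise, 76 had both fall and 1 had calls in opposite directions, and in 626 of the remaining 660 the uncalled probe had the sign of the called one.

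The share of called probes that rose was 72.0%, and it was 55.9% of 2278 with the scanner software's processed signals and 95.1% of 1803 with median centring in place of loess. The count was 3284 in a joint model of the 4 treatments and fell to 616 with the slide as a block, to 687 from the arrays of this comparison alone, to 1111 without replicate 1 and to 1274 without replicate 3, and no slide held more than 1 array of a comparison, too few for a value within a slide. The slide block also takes up replicate 3, which lay alone on its slide.

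The fold changes of CS+2R over C were also set against those of RCH over C in the same model. The difference passed for 603 probes, 512 higher and 91 lower after cold shock, under 436 transcript names. By at least 2-fold, 97 probes were higher and 6 were lower, and the called differences ran from -4.70 to 4.65 on the log2 scale. Of 134 transcripts whose 2 probes were both called for the difference, 122 were higher in both and 12 lower in both. With median centring 433 were higher and 26 lower, with processed signals 507 and 145, and with the slide as a block 344 probes passed in all. Across the 25217 probes, which are not independent replicates, the fold changes of RCH and of CS+2R correlated with r = 0.213 (rho = 0.295). Simulated unchanged groups against the same control pools gave r = 0.0924 and a covariance of 0.000727, beside an observed covariance of 0.00373. The simulation held only differences between pools and independent differences between arrays. Residuals of arrays with different replicate numbers, from different comparisons, correlated between -0.46 and 0.51. For arrays with the same control pool the range was -0.24 to 0.28. Arrays may thus share differences that the simulated values lack. When each comparison kept 2 arrays that shared no control pool, r was 0.354. Without RCH vs C replicate 1, r was 0.10 beside a simulated 0.0764 for the same arrays (covariance 0.0019 beside 0.000702), and without RCH vs C replicate 2 it was 0.146 beside 0.101. Without replicate 3 it was 0.186 beside 0.0783, and without replicate 4 it was 0.287 beside 0.0615 (covariance 0.00648 beside 0.000562). The fold changes of RCH and of RCH+CS+2R correlated with r = 0.0772, below the simulated 0.127, with a covariance of 0.00134 beside a simulated 0.000999 and the same sign at 53.3% of probes beside a simulated 54.0%.

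The comparison of RCH+CS+2R with C asked the same of flies hardened before the shock. Here 1673 probes passed, 1314 that rose and 359 that fell, under 1238 transcript names, and 114 rose and 5 fell by at least 2-fold. The same transcripts led. UF_Scr_NF_100073 rose by 4.00 ± 0.15 (SD, n = 4) on the log2 scale, 16-fold (limma adjusted p = 1.64e-17), and UF_Scr_NF_100094 by 3.82 ± 0.34 (SD, n = 4), 14.1-fold (limma adjusted p = 1.11e-15). UF_Scr_AF_114530 was at -4.56 ± 0.19 (SD, n = 4), 23.6-fold lower (limma adjusted p = 5.52e-17), and at -5.36 with an offset of 0 and -5.86 with processed signals. UF_Scr_AF_104655 (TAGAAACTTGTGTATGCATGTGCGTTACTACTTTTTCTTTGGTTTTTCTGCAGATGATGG) was at -1.56 ± 0.72 (SD, n = 4), 2.95-fold lower (limma adjusted p = 0.00153), with one array, replicate 3, at -0.50. In CS+2R flies the same probe was at -0.66 ± 0.59 (SD, n = 4) and did not pass (limma adjusted p = 0.172), and in the direct comparison of both treatments it was at -0.17 ± 1.1 (SD, n = 4), above 0 on 3 of 4 arrays, and did not pass (limma adjusted p = 0.864). Among 754 transcripts with 2 probes and a call on either, 312 had both probes rise, 56 had both fall and 0 had limma calls in opposite directions.

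The lists of called probes of the 2 cold-shock treatments shared 868 rising and 203 falling probes, where independent lists of these sizes would share 79.7 and 8.47, and 0 probes were called by limma in opposite directions. Simulated unchanged groups against the same control pools shared 0 probes called by limma in each of 100 draws, but they held at most 2 calls per comparison, so this count does not test the shared pools. The 1071 shared probes lay under 767 transcript names, and 93 of them, under 52 names, rose by at least 2-fold in both. Across all 25217 probes the fold changes of both treatments correlated with r = 0.801 (rho = 0.551). The simulated unchanged groups gave r = 0.0919, a value that may lack differences the arrays share beyond their pools. The observed covariance was 0.0328 against 0.000725 in the simulation, a difference of 0.0320. With the control pools split so that each comparison kept 2 arrays that shared none, r was 0.672 and the covariance 0.0336.

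Of the 1673 called probes of RCH+CS+2R, 78.5% rose, against 64.9% of 2044 with the scanner software's processed signals and 92.1% of 1030 with median centring. The count was 3203 in the joint model of the 4 treatments, 1098 with the slide as a block, 959 without replicate 1 and 1027 without the 3 arrays that stood apart in spike-in ratio.

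**Figure D2:**
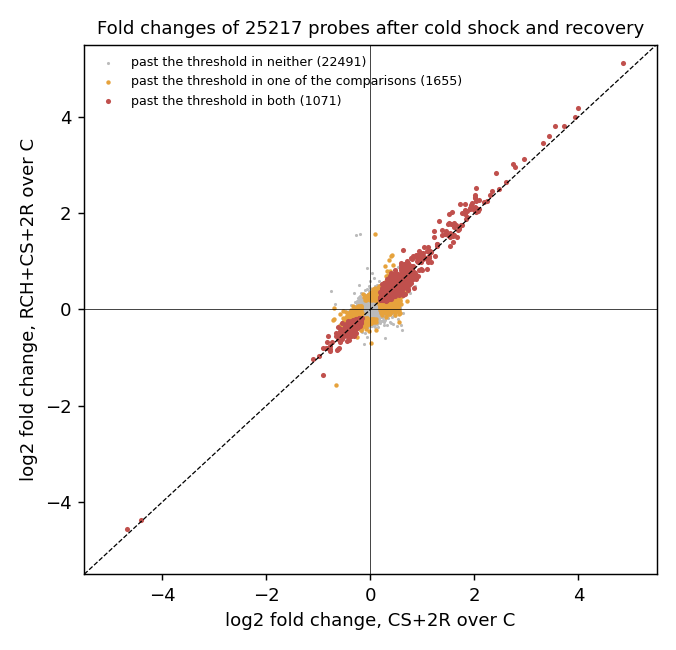
log2 fold change of each of 25217 probes in CS+2R over C (horizontal axis) and in RCH+CS+2R over C (vertical axis), with the diagonal dashed. The 1071 probes past the threshold in both comparisons lie near the diagonal from the strongest fall to the strongest rise, 1655 passed in one comparison, and 22491 in neither.

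The direct comparison of RCH+CS+2R with CS+2R asked what hardening changed in flies that had all been shocked. A single transcript passed the test. UF_Scr_AF_123074 (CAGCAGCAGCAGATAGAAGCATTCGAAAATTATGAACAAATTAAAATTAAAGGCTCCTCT) had a log2 ratio of -0.64 ± 0.24 (SD, n = 4), 1.56-fold lower in the hardened flies and lower on all 4 arrays (limma adjusted p = 0.0115). Its log2 ratio was -0.42 ± 0.15 (SD, n = 4) in RCH+CS+2R over C (limma adjusted p = 0.00291), -0.30 ± 0.17 (SD, n = 4) in RCH over C (limma adjusted p = 0.919) and 0.11 ± 0.11 (SD, n = 4) in CS+2R over C (limma adjusted p = 0.472). UF_Scr_AF_108376 was at -0.44 ± 0.21 (SD, n = 4) and did not pass (limma adjusted p = 0.125), though it passed under 3 of 34 alternatives, among them the joint model at -0.43 (limma adjusted p = 0.00596). Its log2 ratio over C was 0.46 ± 0.12 (SD, n = 4) in CS+2R, which passed (limma adjusted p = 0.000379), and 0.04 ± 0.15 (SD, n = 4) in RCH+CS+2R, which did not (limma adjusted p = 0.826). The rises with the smallest p were those of UF_Scr_AF_108079, at 0.34 ± 0.07 (SD, n = 4), and UF_Scr_UN_144345, at 0.63 ± 0.31 (SD, n = 4), and neither passed (limma adjusted p = 0.204 and 0.247). The leading transcripts of the shock response had direct ratios close to 0, with UF_Scr_NF_100073 at 0.14 ± 0.19, UF_Scr_NF_100094 at 0.08 ± 0.15 and UF_Scr_AF_114530 at 0.04 ± 0.13 (SD, n = 4).

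An unadjusted p under 0.05 was found for 2520 probes (9.99%) in the direct comparison, for 934 with median centring, 605 with every local background as given and 1122 without replicate 3. The indirect estimate, RCH+CS+2R over C minus CS+2R over C, had 0 limma calls and 1265 probes (5.02%) with an unadjusted p under 0.05. Across probes, the direct and indirect estimates of this difference correlated with r = 0.292, although part of their RNA pools was the same. The single direct call, UF_Scr_AF_123074, did not pass with the slide as a block (-0.69, limma adjusted p = 0.124), where 7 other probes did, nor without replicate 1, 3 or 4 (-0.54, -0.64 and -0.64, limma adjusted p = 0.294, 0.158 and 0.172). Over all alternatives its log2 ratio ran from -0.75 to -0.54 and its adjusted p from 0.000795 to 0.960. In simulated data, 91.0% of probes changed by 0.5 on the log2 scale were recovered in this comparison. As for RCH, the simulated noise was independent between arrays and many changed probes were planted together.

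**Figure D3:**
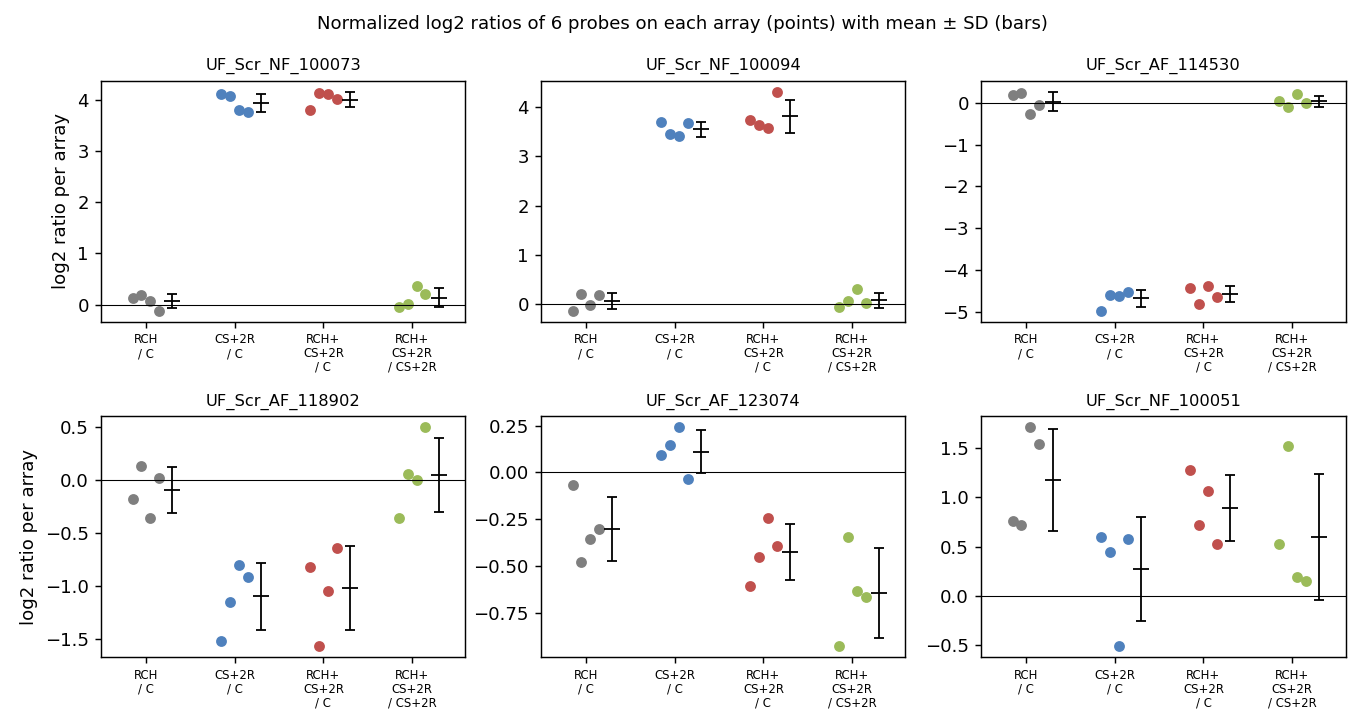
Normalized log2 ratios of 6 probes on each array (points, 4 per comparison) with the mean and SD (bars) in the 4 comparisons, each panel on its own vertical axis. UF_Scr_NF_100073 and UF_Scr_NF_100094 lie near 4 and UF_Scr_AF_114530 below -4 after cold shock with and without hardening, while UF_Scr_AF_123074 is below 0 on every array that set hardened flies against unhardened ones.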

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

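The fit with the slide as a block was planned, but its use as a test of the slide as an explanation, and the tests of the spike-in arrays, were chosen after the results they bear on had been seen. Those of other groupings and of the control pools were chosen before.

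The response to cold shock and recovery differed from that to hardening alone: the contrast of CS+2R over C with RCH over C called 603 probes. Dividing the same 8 arrays in other ways 4 against 4 gave at most 1 call, so 1 of 35 splits, the real one, gave as many. These splits treat the arrays as exchangeable, although arrays of both comparisons share 3 control pools and some slides. The other splits also mix both treatments within a group, which widens the spread of responding probes. Chance is therefore made less likely for this count but not excluded. With the slide as a block the contrast called 344 probes, which argues against the slide as its whole cause. RCH vs C replicate 2 and CS+2R vs C replicate 3 lay alone on their slides, so that fit rests on the remaining arrays. When only arrays whose 3 control pools stand in both comparisons were kept, so that the same control RNA lay on each side, 436 probes were called, 413 of them among the 603, which argues against the control pools as its whole cause. The treatments themselves, which differ in temperature and in the 2 h of recovery, stay open as explanations and are not separated by the design, because hardened flies were sampled with no recovery.

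Each direct count rests on 4 arrays, whose signs can be turned in 8 ways, too few for a share under 0.05. The real counts were 2124 for CS+2R, 1673 for RCH+CS+2R and 1 for the direct comparison, each in 1 of 8 sign patterns, with 2, 2 and 0 as the highest of the others. Turning the sign of some arrays moves a response into the spread, so few calls are likely in the other patterns whatever the cause. RCH over C had 0 limma calls in all 8 patterns, the highest of the others being 0, beside 1251 probes at an unadjusted p under 0.05. For the indirect contrast of RCH+CS+2R with CS+2R, which had 0 limma calls beside 1265 probes at an unadjusted p under 0.05, the splits decide nothing, since all 35 must give at least 0, and the highest of the others gave 107. That split set CS+2R vs C replicates 1, 3 and 4 and RCH+CS+2R vs C replicate 2 against the other arrays. Control pools C-3 and C-4 lay on its one side only, C-1 and C-2 on the other side only, and C-5 on both. This split was singled out as the highest of 35, so its match with part of the control pools may be chance. Residuals of array pairs with the same control pool had a median correlation of 0.015, and 3 of 10 pairs exceeded 0.1. The source of the 107 calls was not tested.

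A signal outside the probe comparisons stood apart on 3 arrays. The median log10 ratio of 320 spike-in spots was 2.05 on CS+2R vs C replicate 4, -1.25 on RCH+CS+2R vs C replicate 1 and -1.36 on RCH+CS+2R vs CS+2R replicate 2, against -0.203 to -0.0237 on the other 13 arrays. A failure of the whole Cy3 channel is argued against by the share of probes well above background in Cy3, which lay inside the range of the other arrays on 3 of the 3 (50.7% to 51.7%, against 49.3% to 56.6%). The amount of spike-in added to a labelled pool is a candidate explanation: 2 of the 2 arrays with pool RCH+CS+2R-2 in Cy3 were displaced in the same direction, while the pool on the remaining array, CS+2R-5, was hybridised once. No biological explanation was tested. Without these 3 arrays 1494 probes passed in CS+2R over C, 1027 in RCH+CS+2R over C and 524 in the contrast with RCH.

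Single outlying arrays were sought with Dixon's test, which flags about 1 group in 20 by chance, in 75 groups of 4 values, 51 of them a named probe in a comparison and 24 a quality value. Named probes outside the comparison they were chosen for were added after the results had been seen. In all, 3 groups stood out. The log2 ratio of UF_Scr_AF_104655 in RCH+CS+2R over C was -0.495 on replicate 3 and between -2.07 and -1.80 on the other arrays. That of UF_Scr_NF_100051 in CS+2R over C was -0.511 on replicate 3 and 0.446 to 0.597 on the others, and that of UF_Scr_UN_144345 in RCH+CS+2R over C was -0.0411 on replicate 4 and 0.466 to 0.541 on the others.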

How the results depend on the processing

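The alternatives that left out the 3 arrays with displaced spike-in ratios and that used every local background as given were chosen after seeing the data. The cause of a change was not tested except where fewer arrays or a stricter criterion explain it by construction. RCH over C had 0 limma calls (1251 probes at an unadjusted p under 0.05) except from its own arrays alone (3), with the slide as a block (8), without the 3 spike-in arrays (2) and with every background as given (1). For CS+2R over C (2124), RCH+CS+2R over C (1673) and the direct comparison (1), in that order, the counts were 551, 634 and 0 with the replicate number as a block, 616, 1098 and 7 with the slide as a block, 3284, 3203 and 5 in the joint model of the 4 treatments, and 99, 119 and 0 with a minimum change of 2-fold. From a comparison's own arrays alone they were 687, 1323 and 0, with median centring 1803, 1030 and 0, and without the 3 spike-in arrays 1494, 1027 and 3. The direct count was also 0 with a normexp offset of 0 and with processed signals. With every background as given the counts were 1720, 1859 and 1. The contrast of CS+2R with RCH (603) was 344 with the slide as a block and 459 to 675 under the other 32 alternatives fitted for it, and the indirect contrast gave 0 limma calls (1265 probes at an unadjusted p under 0.05) under all 33.

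With each array left out in turn, the counts were 0 to 0 for RCH, 1111 to 2291 for CS+2R, 959 to 1841 for RCH+CS+2R, 0 to 2 for the direct comparison, 464 to 623 for the contrast with RCH and 0 to 0 for the indirect contrast. CS+2R without replicate 1 gave 1111 and without replicate 3 gave 1274, and RCH+CS+2R without replicate 1 gave 959. The correlation between both cold-shock treatments was 0.672 with the control pools split and otherwise 0.719 to 0.825, and that of RCH with CS+2R was 0.10 to 0.35. Replicate numbers do not pair the arrays: of 24 pairs with the same number, residuals of 5 correlated above 0.1, and 0 of 16 arrays correlated best with one of its own number. Over 555 values of named probes under alternatives, 539 kept direction and side of the threshold, 9 lost the call, 7 gained it and 0 changed sign. Signal over background of 1.40 to 1.79 limits what dim probes can show.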

Other observations

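The test of brightness was fixed after the pattern had been noticed and before its own result was seen, and its matching was made finer after a coarser one had come out on the same side.

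A small part of the array carried sequences under database accessions in place of contig-style names, and these responded to cold shock far more often than the rest. Only probes with NF or AF in their ID entered this comparison, so part of the tested transcript names was left out. Of 26 such sequences, each represented by its brightest probe, 8 rose in CS+2R over C, 6 of them by at least 2-fold, against 6.58% of 10192 other sequences (Fisher's exact test, two-sided, p = 0.000195, adjusted over the 4 comparisons p = 0.00039). In RCH+CS+2R over C, 9 of the 26 rose and 6 did so by at least 2-fold, against 5.84% of the others (Fisher's exact test, two-sided, p = 1.05e-05, adjusted p = 4.2e-05). By limma 0 of the 26 brightest probes fell, with 1 and 3 falling at an unadjusted p under 0.05. Among all 89 tested probes with NF in their ID, limma called 25 that rose and 1 that fell in CS+2R over C. In RCH+CS+2R over C, 28 rose and 1 fell. In RCH over C and in the direct comparison, 0 of the 26 were called by limma, and 2 and 7 had an unadjusted p under 0.05. The accession-named sequences were brighter than the rest, with a median mean log2 intensity of 13.2 against 8.69, and brightness of the probes is a possible explanation, since bright probes are called more easily. Among 10000 random sets of 26 other sequences, each drawn from the 100 nearest in brightness, the median was 2 risers in CS+2R over C and the highest 10, a resampling p of 0.0005 for the observed 8. In RCH+CS+2R over C the median was 1 and the highest 7, so that no set held the observed 9, and the resampling p of 0.0001 is the smallest these draws can give. Both the draws and Fisher's test treat sequences as independent, so their p-values are too small if related sequences rise together. Fisher's test also describes a pattern first noticed in these same data. This argues against brightness as the whole cause. That these sequences had been put on the array for a known response to stress remains a hypothesis, which was not tested because no gene was named, and several of them may represent related transcripts.

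UF_Scr_NF_100051, chosen for its small p in RCH over C, was at 1.18 ± 0.52 (SD, n = 4) in RCH over C and at 0.60 ± 0.64 (SD, n = 4) in RCH+CS+2R over CS+2R, neither of which passed (limma adjusted p = 0.454 and 0.431), and at 0.90 ± 0.34 (SD, n = 4) in RCH+CS+2R over C, which passed (limma adjusted p = 0.0142). In CS+2R over C it was at 0.28 ± 0.53 (SD, n = 4), with replicate 3 at -0.51, and did not pass (limma adjusted p = 0.490). By the labels, RCH over C and RCH+CS+2R over CS+2R share no RNA pool. RCH+CS+2R over C and CS+2R over C each share pools with both of them, so those values are not independent. No value for an unchanged probe was computed. In RCH over C its limma adjusted p ran from 0.0313, with the slide as a block, to 0.999 over the alternatives. RCH vs C replicate 2 has no weight in the fit with the slide as a block.

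The 93 probes that rose by at least 2-fold in both cold-shock comparisons had a median log2 ratio of 0.11 in the direct comparison of hardened with unhardened shocked flies. Their median was 0.06, 0.08, 0.26 and 0.07 on its 4 arrays, and 0 of the 93 were called there by limma, beside 34 at an unadjusted p under 0.05, while an exact sign-flip test of 4 arrays cannot give a two-sided p below 0.125. Over all 25217 probes of the direct comparison, the median was 0.0012 and 9.99% had an unadjusted p under 0.05. In RCH over C the median of the 93 probes was -0.0052. Part of the RNA pools of the direct arrays also stood on the arrays that chose these probes.

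The 2 probes of a transcript read the same RNA pools on the same arrays, so they share differences between pools as well as responses to cold. Across 7960 transcripts, which are not independent replicates, the r between probes was 0.471 for RCH over C, 0.689 for RCH+CS+2R over CS+2R, 0.872 for CS+2R over C and 0.894 for RCH+CS+2R over C. With the signs of the 4 arrays turned in the 7 other ways, r ran from 0.345 to 0.610, 0.423 to 0.686, 0.564 to 0.807 and 0.326 to 0.777 in the same order. The value for RCH over C thus lay inside its range, and 8 patterns are too few for a share under 0.05 in the others. Some of the turned patterns keep part of a response, so their ranges are not those of unchanged transcripts.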
